A study of Mus musculus with 4 samples.

How the data were processed

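Total RNA from 4 mouse brown adipocyte samples was labelled with biotin and hybridised to single-colour Affymetrix arrays that carry only perfect-match probes, per the labels' protocols. The deposited table holds 1 log2 expression value per probe set and array; the authors' tools were RMA (background correction, quantile normalization and median-polish summary), affy and limma, per the submitters' processing notes, which give no versions, settings or order. That the values are on the log2 scale was read from their range of 2.70 to 13.3. Raw probe intensities were not used here, so the background correction and summary could not be varied, and RMA compresses the fold changes of dim probe sets. The table holds 23634 probe sets. How they were chosen from those on the array is not given in the sources used here. Genes of the lists below for which no probe set was named with exactly 1 gene symbol were not analysed here (Ppargc1a, Zic1 and Plin1 among the genes to be named). All 4 value columns were used.

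Probe sets were named from GEO's platform annotation. Of the 23599 tested probe sets 16692 had 1 gene symbol, 372 had several and were left unnamed, and 6535 had none there. The Entrez ID of 16639 of the named probe sets was found in the reference table (GRCm38.p6), and no symbol needed an update. No genome was given, so no coordinates are printed. These probe sets cover 10926 genes, 3879 of them by several probe sets. A gene was represented by its probe set with the highest mean over all 4 arrays, a choice that does not use the groups. Of the 134 genes that passed, 43 had 60 further probe sets, of which 57 changed in the same direction (16 of them past the threshold) and 3 in the opposite direction, none with an unadjusted p under 0.05.

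Groups and replicate numbers were taken from the sample titles. The 2 Blnc1 arrays were compared with the 2 vector arrays by linear models with moderated variances (limma 3.58.1 in R 4.3.3: lmFit and eBayes, two-sided, no covariate, no filter on level), with Benjamini-Hochberg adjustment over the 23599 probe sets and a threshold of 0.05. The prior carried 3.95 degrees of freedom and an SD of 0.092 log2 units. Fold changes are Blnc1 over vector. With 2 arrays per group, chance alone puts both arrays of one group on the same side of the other group for 33.3% of probe sets; the observed share was 50.4%. Gene lists were tested with camera at a preset correlation of 0.01, on 1 probe set per gene and with adjustment over the 20 lists. They were tested again with an estimated correlation and with fry. Camera compares a list's genes with all other genes. At the preset correlation it counts genes as nearly independent, so its p-values rest mainly on the genes and not on the spread between arrays. With an estimated correlation it uses the few residual degrees of freedom of 4 arrays and has little power. The genes to be named were fixed as a rule: the Blnc1 transcript, the 15 largest rises and 15 largest falls among genes past the threshold, the 4 members of each list with the smallest p, and a fixed set of brown and general adipocyte genes. The design, these 20 lists, this rule and all alternatives but the one without Y-linked genes and Xist were fixed before the data were examined. Arrays were simulated with the vector means and with variances drawn from the fitted prior whatever the level (23599 probe sets, 5 runs with 200 changed probe sets each). On these the test recovered 26.3% of 1.5-fold, 86.9% of 2-fold and 99.4% of 4-fold changes, and 4.85% of its calls were false. Such arrays follow the model that the test assumes, so these rates need not hold for the real arrays. A list shifted by 0.15 log2 units was called in 5 of 5 runs, and no list was called without a shift; the simulated genes were independent of each other.

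The alternatives were other variance priors, repeated quantile normalization, median centring, filters on dim probe sets, leaving out probe sets prone to cross-hybridisation, the mean of a gene's probe sets, other thresholds, a test against a minimum fold, a test without moderation, the replicate number as a block, and leaving out each array; a count without Y-linked genes and Xist was added after seeing the data. No slide or scan date is given in the sources used here. As a sign of RNA quality, the log2 difference between the 3' and 5' control probe sets was 0.41 in vector and 0.28 in Blnc1 arrays for Gapdh, and 1.51 and 1.34 for Actb.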

Results

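Gene expression was measured in mouse brown adipocytes, the heat-producing cells of brown fat, that carried either an empty vector or a vector expressing the long noncoding RNA Blnc1 (brown fat lncRNA 1). Preadipocytes of both kinds were differentiated for 6 days, and total RNA was hybridised to Affymetrix mouse PM Strip arrays, which read the 3' part of each transcript. There were 4 arrays, 2 for each group. The table held 23599 probe sets besides 35 control probe sets. The array medians lay between 5.98 and 6.04 on the log2 scale. Replicate arrays differed by a median of 0.091 (vector) and 0.10 (Blnc1) log2 units per probe set, and arrays of different groups by 0.13 to 0.14. All 18 hybridization control probe sets, which read spiked-in transcripts, were lower in the Blnc1 arrays (median difference -0.27). The 3' minus 5' difference of the Gapdh and Actb control probe sets, a sign of RNA quality, was also lower in both Blnc1 arrays than in both vector arrays, by -0.13 and -0.17 (Blnc1 minus vector). The labels call the replicates biological but do not say whether they came from separate transductions. The p-values of single genes therefore measure only the spread between these arrays, and the number of arrays limits the precision.

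The expressed transcript itself was examined first, as a check of the labels. The platform annotation names 2 probe sets after C730029A08Rik, a symbol that the reference gene table gives, together with Blnc1, as a synonym of Paqr9. The brighter probe set read 8.11 ± 0.041 (SD, n = 2) in vector cells and 12.74 ± 0.0092 (SD, n = 2) in Blnc1 cells, a 24.8-fold rise (log2 fold change 4.63 ± 0.077 SE, adjusted p = 3.73e-05 by limma with Benjamini-Hochberg adjustment). It was the largest change among all genes past the threshold, and the Blnc1 arrays lay near the top of the arrays' scale, where readings are compressed, so the fold can be understated. The dimmer probe set had a log2 fold change of -0.31 ± 0.14 (SE) and did not pass the test (limma adjusted p = 0.315). A 3' probe set outside the expressed sequence would not report the vector transcript, and the positions of these 2 probe sets were not analysed here. The probe set named Paqr9 had a log2 fold change of -0.50 ± 0.11 (SE), which did not pass either (limma adjusted p = 0.0905).

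The main comparison asked how forced expression of Blnc1 changed the transcriptome of differentiated brown adipocytes. The 2 largest rises after Blnc1 itself were in the brown fat genes Cidea and Ucp1. Cidea, a lipid droplet protein abundant in brown fat, rose 8.71-fold (log2 fold change 3.12 ± 0.094 SE, limma adjusted p = 4.43e-04), from 7.34 ± 0.042 to 10.46 ± 0.13 (SD, n = 2 each). Ucp1, the mitochondrial uncoupling protein, rose 7.99-fold (log2 fold change 2.997 ± 0.078 SE, limma adjusted p = 2.70e-04), from 5.01 ± 0.0015 to 8.01 ± 0.053 (SD, n = 2 each). Mb, which encodes the oxygen-binding haem protein myoglobin, rose 4.72-fold on its brighter probe set, while its other probe set stayed near the floor of the array with a log2 fold change of -0.012. Cpt1b, which admits long-chain fatty acids to mitochondria, rose 2.58-fold, and the cytochrome c oxidase subunit isoforms Cox7a1 and Cox8b rose 2.42-fold and 2.19-fold. Across all probe sets 219 passed an adjusted p of 0.05 (limma, Benjamini-Hochberg), 147 higher and 72 lower in Blnc1 cells. Counted with 1 probe set per gene, 134 of 10926 genes passed, 94 higher and 40 lower, of which 30 changed by at least 2-fold (25 higher and 5 lower). After centring each array on its median the split was 108 higher and 79 lower genes. Adjusted p under 0.05 was reached by 22 genes without vector replicate 1, 23 without vector replicate 2, and 3 genes without either Blnc1 array; C730029A08Rik, Ucp1 and Cidea passed in every one of these 4 fits.

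**Figure D1:**
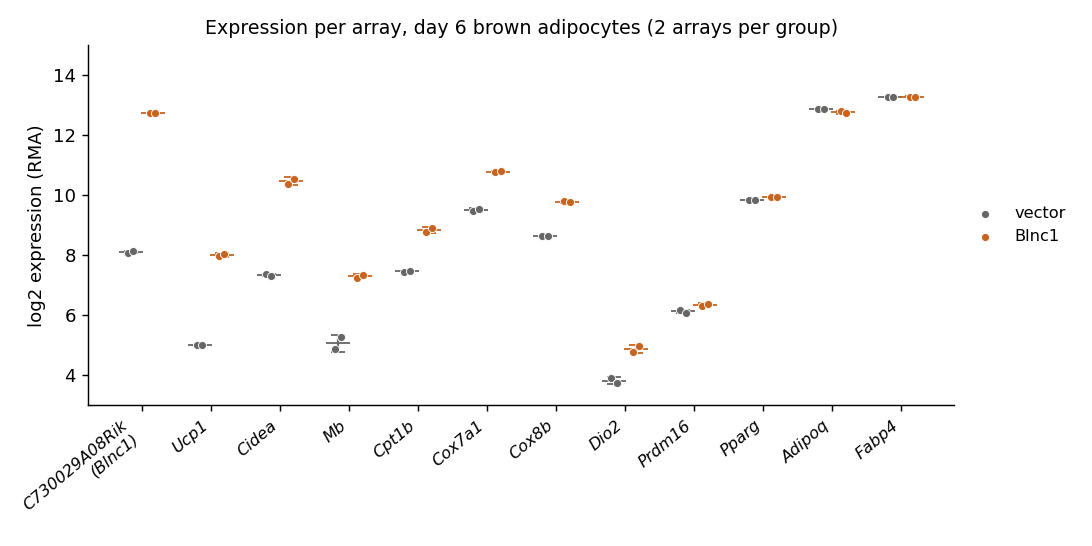
Log2 expression (RMA) of the Blnc1 transcript, 7 genes that passed the test and 4 that did not (Prdm16, Pparg, Adipoq and Fabp4), by gene; points are arrays, horizontal bars the mean of 2 arrays and error bars the SD (grey, vector; orange, Blnc1). Ucp1 and Cidea lay about 3 log2 units higher in Blnc1 cells, and the means of Pparg, Adipoq and Fabp4 lay within 0.12 log2 units of each other in the 2 groups.

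The 15 largest rises held several secreted or plasma proteins besides the brown fat genes. Itih4 and Itih5, heavy chains of the inter-alpha-trypsin inhibitor family, rose by log2 fold changes of 1.67 ± 0.16 and 1.54 ± 0.087 (SE). Kng1, the precursor of the kinins, rose by 1.57 ± 0.11. Fgl1, a fibrinogen-like secreted protein, rose by 1.26 ± 0.17 from a dim vector mean of 4.10. Hmox1, the inducible haem oxygenase, rose 2.71-fold. Stbd1, a glycogen-binding protein, rose 2.81-fold, Calhm6 2.38-fold and the calcium-binding protein S100b 2.26-fold. The remaining gene among the 15, 2610528A11Rik, rose 2.94-fold. The adjusted p of these 9 genes lay between 0.0112 and 0.0454 (limma).

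Falls were smaller than rises. P2rx3, an ATP-gated ion channel, had the largest, with a log2 fold change of -1.36 ± 0.078 (SE, limma adjusted p = 0.0112), while its other 2 probe sets stood at -0.24 and -0.25 and did not pass. It was followed by the interferon-inducible GTPase Gbp3 (-1.19 ± 0.16), and the folate enzyme Aldh1l1 stood at -1.03 ± 0.10. Smaller falls were found for the adenosine deaminase gene Ada (-0.96), the phosphatase inhibitor Ppp1r1a (-0.89), Wfdc21 (-0.86), Cyp2e1 (-0.83), the secreted Wnt modulator Sfrp2 (-0.82), the peroxisomal transporter Abcd2 (-0.80), Lgals3bp (-0.80), the glycerolipid enzyme Gpat3 (-0.77) and the matrix protein asporin, Aspn (-0.77). Ada, Cyp2e1 and Abcd2 were dim, with vector means between 4.36 and 4.87. The other 2 probe sets of Abcd2 stood at -0.23 and -0.075 and did not pass. The other 3 of the 15 largest falls were the Y-linked genes Eif2s3y, Uty and Kdm5d, at -1.18 ± 0.078, -1.02 ± 0.11 and -0.87 ± 0.087 (SE, limma adjusted p 0.0120 to 0.0341). Of the 6 measured Y-linked genes the other 3, named after their values were seen, did not pass. Sry stood at -0.27 ± 0.12 (SE), on a probe set prone to cross-hybridisation with a vector mean of 5.77, below the array medians. The dim Usp9y and Zfy1 stood at -0.021 ± 0.14 and 0.11 ± 0.080 (SE). Xist, the X-linked RNA expressed from the inactive X of female cells and looked at after these values were seen, rose by 0.55 ± 0.077 (SE, limma adjusted p = 0.0479), from 10.80 ± 0.026 to 11.35 ± 0.032 (SD, n = 2 each). These shifts went together with every gene group described below, since they separated the same 2 groups of arrays.

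**Figure D2:**
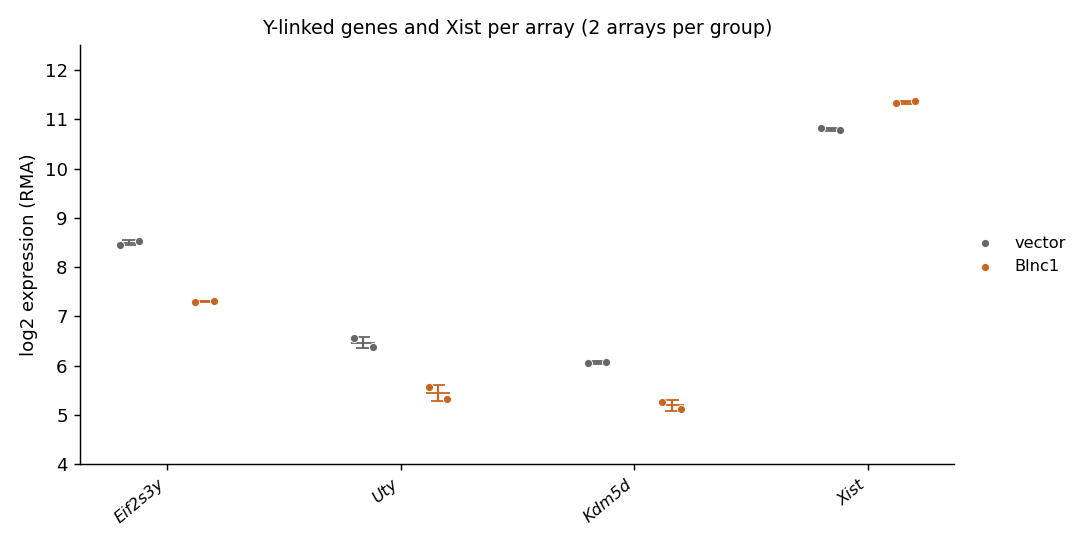
Log2 expression (RMA) of 3 Y-linked genes and Xist, by gene; points are arrays, horizontal bars the mean of 2 arrays and error bars the SD (grey, vector; orange, Blnc1). Eif2s3y, Uty and Kdm5d were lower by 0.87 to 1.18 log2 units in both Blnc1 arrays and Xist higher by 0.55.

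The gene lists fixed in advance were then compared between the groups. Camera p-values with the preset correlation rest mainly on the number of genes in a list, not on the 4 arrays. Brown thermogenic genes were higher as a group: of 23 measured members 9 rose and none fell, 21 had a positive log2 fold change, and the median was 0.38 (camera, preset correlation, adjusted p = 1.51e-11). The list did not pass with an estimated correlation (camera adjusted p = 0.221). Adjusted over the list alone, 17 rose and 1 fell. Besides Ucp1, Cidea, Cox7a1 and Cox8b, the thyroid hormone activating deiodinase Dio2 rose 2.07-fold from a dim level of 3.82 ± 0.13 (SD, n = 2). The other 4 members that passed, named after their values were seen, were Pdk4, a kinase that inhibits pyruvate dehydrogenase (0.92), Plin5, a lipid droplet protein of oxidative tissues (0.77), Mpzl2 (0.73) and the mitochondrial deacetylase Sirt3 (0.64). Elovl3 and the transcription factors Ebf2 and Prdm16 did not pass, at log2 fold changes of 0.27 ± 0.083, 0.38 ± 0.082 and 0.22 ± 0.081 (SE).

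Among 35 measured transcription regulators of brown adipogenesis only Ppara, a nuclear receptor that drives fatty acid oxidation genes, passed over all probe sets, with a log2 fold change of 0.73 ± 0.095 (SE, limma adjusted p = 0.0434), and its other 2 probe sets passed as well (0.87 and 1.01). Adjusted over the list alone, 5 rose and 4 fell. The list as a whole did not shift (median 0.036, camera adjusted p = 0.844). The nearest other members were Thrb at -0.49, Nr4a1 at -0.73 and Esrrg at 0.40.

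General adipocyte genes did not shift as a group, with members on both sides. Of 22 measured members 1 rose and none fell, and adjusted over the list alone 3 rose and 1 fell. Both arrays of one group lay above both of the other for 18 members, 9 in each direction, against 53.2% of all genes here and 33.3% by chance. In fry, the test for changes in either direction gave an unadjusted p of 0.00212. The same fry test gave 0.00177 for the transcription regulators and 0.0163 for lipogenesis genes, so a small value was not particular to this list. Their median log2 fold change was -0.022 and their mean 0.032, and the sign of the set test differed between methods (camera, adjusted p = 0.939, lower; fry, adjusted p = 0.351, higher). The member that passed was Trarg1, a regulator of glucose transporter trafficking, at 0.65 ± 0.075 (SE). Pparg, the master regulator of adipogenesis, stood at 0.10 ± 0.075 (SE), Cebpa at -0.23 ± 0.088, Cebpb at 0.30 ± 0.076 and the adipokine Adipoq at -0.12 ± 0.077. Fabp4 was at 0.0016 ± 0.075, a value that turned negative after median centring, and lay near the top of the array's scale at 13.28 in both groups. Rbp4, at 0.76 ± 0.15, and the monoacylglycerol lipase Mgll, at -0.34 ± 0.077, did not pass on the probe sets used, though a further probe set of Mgll did (-0.64, limma adjusted p = 0.0375). Of 16 measured lipogenesis genes 13 were negative and none passed over all probe sets, 1 rose and 1 fell adjusted over the list alone, and the list did not pass (median -0.092, camera adjusted p = 0.0591). It passed without vector replicate 1 and without Blnc1 replicate 2 (camera adjusted p = 0.0427 and 0.0462), but not without either of the other arrays (0.377 and 0.275). Acacb stood at 0.41, Fads2 at -0.38, Elovl6 at 0.28 and Pnpla3 at -0.22.

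White adipocyte-selective genes were lower as a group. Of 12 measured members 2 fell and none rose, and 6 fell adjusted over the list alone (median -0.27, camera adjusted p = 5.63e-04, but adjusted p = 0.413 with an estimated correlation). Those that fell were the adipokine Retn, resistin, at -0.67 ± 0.081, and the angiotensin precursor Agt at -0.70 ± 0.090 (SE). Hoxc8 stood at -0.76 ± 0.11 and Psat1 at -0.47 ± 0.083, and neither passed.

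Most genes of the respiratory chain, the TCA cycle and the mitochondrial ribosome had small positive log2 fold changes, and few passed on their own. Of 72 nuclear respiratory chain and ATP synthase genes 68 had a positive log2 fold change, with a median of 0.12, but only Cox7a1 and Cox8b passed (camera adjusted p = 9.14e-07, and adjusted p = 0.413 with an estimated correlation); the same number passed adjusted over the list alone. The nearest others were Ndufs4 at 0.31 and Atp5g1 at -0.35. Of 73 mitochondrial ribosomal protein genes 63 were positive, with a median of 0.15, and none passed, also adjusted over the list alone (camera adjusted p = 8.17e-08, and adjusted p = 0.560 with an estimated correlation). Mrps5, Mrpl55, Mrps36 and Mrps23 stood at 0.50, 0.51, 0.39 and 0.52. Between replicates the mitochondrial ribosomal list differed by medians of -0.069 (vector) and -0.080 (Blnc1), replicate 2 being lower in both. Of 17 genes of the TCA cycle and pyruvate dehydrogenase 15 were positive, with a median of 0.15, and none passed, or 1 adjusted over the list alone (camera adjusted p = 0.00176, and adjusted p = 0.341 with an estimated correlation). Sucla2, at 0.38, Ogdh, at 0.30, Idh3g, at 0.28, and Idh2, at 0.28, had the smallest p-values among them. The 62 cytosolic ribosomal protein genes had a median of 0.012, no member passed by either adjustment, and the list did not shift (camera adjusted p = 0.652, with the sign of the shift turned after repeated quantile normalization). Rpl26, Rpl27, Rps14 and Rpl36a lay between 0.12 and 0.13.

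Fatty acid oxidation genes were also higher as a list: 20 of 22 measured members were positive, the median was 0.24, and Cpt1b alone passed over all probe sets, while 10 rose and 1 fell adjusted over the list alone (camera adjusted p = 1.33e-05, and adjusted p = 0.413 with an estimated correlation). The mitochondrial thiolase Acaa2 stood at 0.40 ± 0.076 and the carnitine carrier Slc25a20 at 0.42 ± 0.093 (SE). Cpt1a, the liver-type counterpart of Cpt1b, stood at -0.54 ± 0.079 (SE, limma adjusted p = 0.0526). Glycolysis and hypoxia genes had a median of 0.38, with 18 of 19 members positive and none past the test over all probe sets, or 7 adjusted over the list alone (camera adjusted p = 3.50e-07, and adjusted p = 0.432 with an estimated correlation). Egln3, an oxygen-sensing prolyl hydroxylase, stood at 1.28 ± 0.20, Ndrg1 at 1.18 ± 0.24, Pfkp at 0.63 ± 0.11 and Pdk1 at 0.48 ± 0.11 (SE). This list also differed between replicates, by a median of 0.20 between the vector arrays and 0.16 between the Blnc1 arrays, replicate 2 being higher in both.

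**Figure D3:**
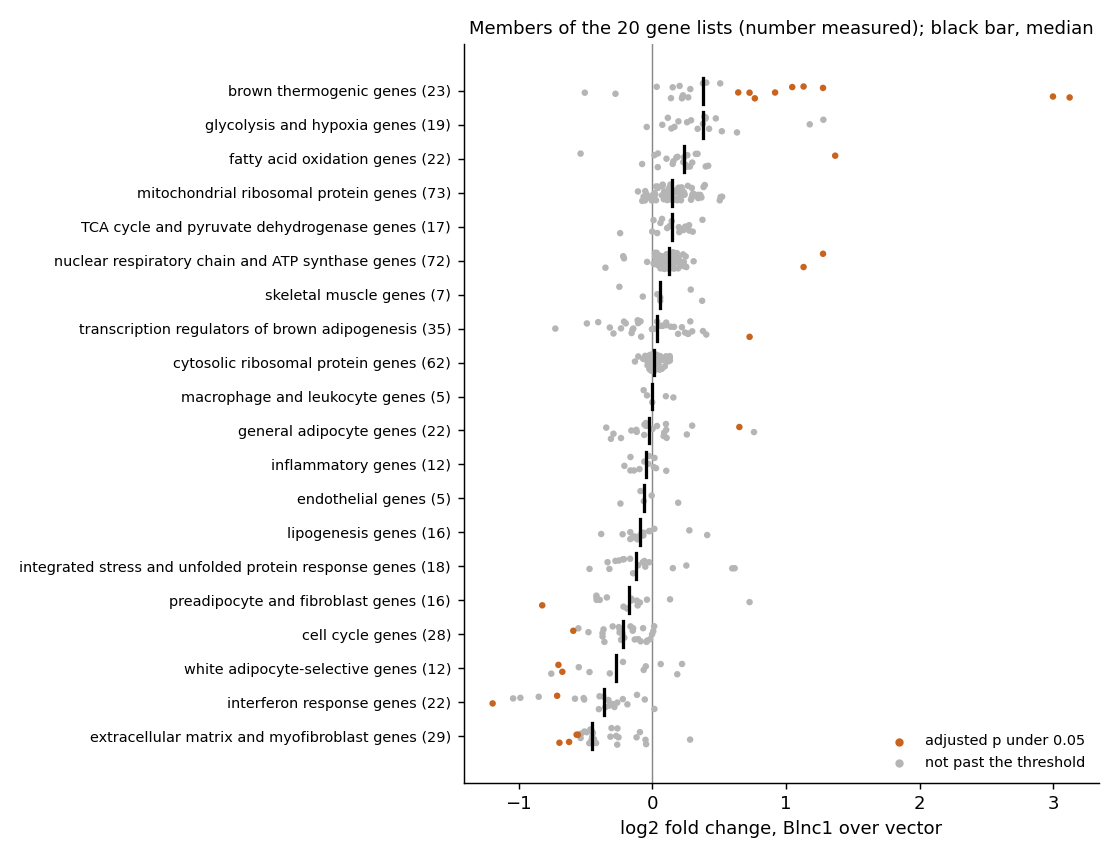
Log2 fold change (Blnc1 over vector) of every measured member of the 20 gene lists, 1 row per list with the number measured; orange points passed an adjusted p of 0.05 (limma), grey points did not, and black bars are list medians. Medians ran from -0.45 for extracellular matrix and myofibroblast genes to 0.38 for brown thermogenic genes.

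Extracellular matrix and myofibroblast genes were lower in Blnc1 cells. Of 29 measured members 28 had a negative log2 fold change, with a median of -0.45, 4 fell and none rose, and 22 fell and 1 rose adjusted over the list alone (camera adjusted p = 3.13e-14, and adjusted p = 0.221 with an estimated correlation). Those that fell were the collagens Col8a1 (-0.69 ± 0.087 SE), Col6a2 (-0.62 ± 0.079) and Col4a2 (-0.56 ± 0.080) and the matricellular protein Postn (-0.57 ± 0.077). Preadipocyte and fibroblast genes had a median of -0.17, with 14 of 16 members negative and only Sfrp2 past the test; adjusted over the list alone 5 fell and 1 rose (camera adjusted p = 0.00111, and adjusted p = 0.341 with an estimated correlation). Dlk1 stood at -0.42, Fst at -0.42 and Klf2 at 0.73. Cell cycle genes had a median of -0.22, with 26 of 28 members negative. Only the mitotic activator Cdc20 fell (-0.59 ± 0.085 SE), and 6 fell adjusted over the list alone (camera adjusted p = 1.85e-07, and adjusted p = 0.413 with an estimated correlation). Ccna2 stood at -0.55, Mki67 at -0.37 and Kif11 at -0.36.

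Interferon response genes were lower as a list. The list also differed between the Blnc1 arrays, by a median of -0.16 (replicate 2 minus replicate 1), against 0.025 between the vector arrays. Of 22 measured members 21 were negative, with a median of -0.36, Gbp3 and the apoptosis-associated Xaf1 (-0.71 ± 0.086 SE) fell, and 15 fell adjusted over the list alone (camera adjusted p = 1.46e-10, and adjusted p = 0.341 with an estimated correlation). Rtp4 at -0.99 ± 0.16 and Gbp2 at -0.85 ± 0.14 (SE) did not pass on the probe sets used, though the further probe set of Gbp2 did (-1.05, limma adjusted p = 0.0239). The integrated stress and unfolded protein response list had a median of -0.12 and no member past the test over all probe sets, or 1 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.0294, and adjusted p = 0.432 with an estimated correlation). Its adjusted p was 0.251 without vector replicate 2 and 0.214 without Blnc1 replicate 1. Psat1, Phgdh and Pdia4 stood at -0.47, -0.32 and -0.33, and Ddit3 at 0.62. Inflammatory genes did not shift (12 measured, median -0.045, camera adjusted p = 0.322, none past the test by either adjustment). Lcn2, Csf1, Ccl2 and Saa3 lay between -0.21 and 0.10.

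Markers of other cell types were few and dim, and none passed by either adjustment. The 5 measured macrophage and leukocyte genes had a median of -5.3e-04 and a mean of 0.031 (camera adjusted p = 0.939), the 5 endothelial genes a median of -0.063 (camera adjusted p = 0.652) and the 7 skeletal muscle genes a median of 0.059 (camera adjusted p = 0.652). Among the leukocyte genes Cd14 read 4.14 ± 0.25 in vector and 4.30 ± 0.19 in Blnc1 cells (SD, n = 2 each), and Adgre1, Fcer1g and Laptm5 had vector means between 4.18 and 4.56. The endothelial genes Flt1, Egfl7, Esam and Eng lay between -0.24 and 0.19, and the muscle genes Des, Tnnc1, Tnnc2 and Myl4 between -0.25 and 0.37. Of the 20 lists 12 passed in camera, 6 higher and 6 lower. With an estimated correlation none of the 12 passed. That test has only the few residual degrees of freedom of 4 arrays, so a pass was unlikely beforehand. Its failures say little about correlation between genes. In fry, which asks only whether a list's own genes moved one way, 5 passed: brown thermogenic genes, nuclear respiratory chain and ATP synthase genes, TCA cycle genes, fatty acid oxidation genes and extracellular matrix genes.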

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

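Among the alternatives given here, the count without Y-linked genes and Xist was chosen after seeing the data. The 134 genes past the threshold kept their direction after averaging of probe sets, as did the 128 of them still tested without cross-hybridising probe sets. They also kept it without each array, but this was fixed in advance. For all 134 both Blnc1 arrays lay on the same side of both vector arrays. Repeated quantile normalization and median centring turned none of them either. These moved the median log2 fold change of all genes only from 0.0073 to -0.0026 and -0.0086, too little to turn such genes. The number past the threshold, however, depended on the settings, among them the variance estimate from 4 arrays, the threshold and the choice of probe sets. Against 219 probe sets and 134 genes, a variance prior that follows the expression level gave 2174 and 1237, keeping the probe sets above the median level 1020 and 612, above the lower quartile 334 probe sets, the mean of a gene's probe sets 467 genes, and an adjusted p under 0.1 958 and 545. A threshold of 0.01 gave 3 and 3, a test against a 1.2-fold change 22 and 13, and the replicate block 30 and 19, of which 17 genes were among the 134. Without moderation 0 and 0 passed in the linear model of limma, although 3204 probe sets and 1706 genes had an unadjusted p under 0.05. Leaving out 1 array at a time, with the lone array assumed to vary like the other group, gave 3 to 38 probe sets and 3 to 23 genes. A robust prior, repeated quantile normalization, median centring, the removal of cross-hybridising probe sets and of Y-linked genes with Xist (205 and 123) stayed within 1.5 times. The arrays were not treated as pairs, since the labels name no shared batch and 2 pairs are too few. Deviations of same-numbered arrays correlated at 0.089 across probe sets, which does not rule out a shared replicate effect on some genes. In replicate 2 of both groups glycolysis and hypoxia genes were higher and mitochondrial ribosomal protein genes lower.

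The Blnc1 transcript stayed past the threshold under the other variance priors, scalings, filters and the block. Its log2 fold change was 4.60 to 4.66 there and without each array. It also stayed past the threshold at 2.16 when its 2 probe sets were averaged, a lower value since 1 of them did not rise. Without moderation it did not pass, but neither did any other gene. Of 20 gene lists 12 passed, against 0 with an estimated correlation, where few residual degrees of freedom left little power, and 5 with fry. The estimated correlation gave an adjusted p of 0.221 for brown thermogenic and extracellular matrix genes, 0.341 for preadipocyte, TCA cycle and interferon genes, 0.413 for white adipocyte, respiratory chain, fatty acid oxidation and cell cycle genes, 0.432 for stress response and glycolysis genes, and 0.560 for mitochondrial ribosomal proteins. Fry gave 0.0917 for white adipocyte, 0.0554 for preadipocyte, 0.178 for mitochondrial ribosomal, 0.122 for cell cycle, 0.0689 for interferon, 0.122 for stress response and 0.149 for glycolysis genes. The stress response list had 0.0614 without cross-hybridising probe sets and 0.0163 to 0.251 without 1 array. The lipogenesis list passed with the replicate block (0.0438) and had 0.0427 to 0.377 without 1 array. Lists far from the threshold changed direction: general adipocyte genes in fry (0.351), above the median (0.868) and above the lower quartile (0.811) and between 0.817 and 0.969 without 1 array; cytosolic ribosomal proteins after repeated quantile normalization (0.920) and at 0.449 to 0.817 without 1 array; transcription regulators without cross-hybridising probe sets (0.987); leukocyte (0.695 to 0.854) and endothelial genes (0.229 to 0.991) without 1 array. Among single genes with no change, the log2 fold change of Fabp4 turned to -0.014 after median centring and ran from -0.0093 to 0.013 without 1 array, and Myl4 turned to 0.047 in the mean of its probe sets. Without 1 array Myl4 ran from -0.15 to 0.0046, Cd14 from -0.018 to 0.33, Laptm5 from -0.23 to 0.15, Eng from -0.16 to 0.037 and Adgre1 from -0.024 to 0.23. The cause of these changes was not tested, apart from the smaller number of probe sets or arrays tested. Dim probe sets limit what can be seen: 34 of the 134 genes had a mean level below the median of the table.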

Other observations

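The lists of cholesterol, haem and iron, and plasma protein genes were written after the values were seen, and of the tests on the explanations below, the one on adipocyte differentiation and the one on loss of the Y chromosome alone were chosen after the values they use were known. Of 19 measured cholesterol synthesis genes 1 fell and none rose; 16 had a negative log2 fold change. Cyp51, the lanosterol demethylase, fell by 0.68 on the log2 scale (limma adjusted p = 0.0455), Msmo1 stood at -0.48 ± 0.082, Dhcr7 at -0.45 ± 0.10 and, in the other direction, Lss at 0.39 ± 0.079 (SE). Among 19 haem and iron genes 3 rose and none fell. They were Mb, Hmox1 and the iron exporter Slc40a1 (0.99 ± 0.077 SE), while the ferritin chains Fth1 and Ftl1 stood at 0.12 and 0.015 and the first enzyme of haem synthesis, Alas1, at 0.38 ± 0.080. Of 16 measured plasma protein genes 5 rose (Itih4, Itih5, Kng1, Fgl1 and the coagulation factor F5, at 0.84). Fgl1 and F5 were dim, with vector means of 4.10 and 3.49. Albumin, Alb, stayed near the array's floor with a log2 fold change of 0.025, and Apoa1 stood at 0.093. None of these 3 lists was tested as a set.

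Of 6 measured Y-linked genes 3 were lower in the Blnc1 arrays (Sry, at -0.27, and the dim Usp9y and Zfy1 did not pass), and the 3 Xist probe sets had log2 fold changes of 0.55, 0.53 and 0.68 and the first of these passed. In vector and Blnc1 arrays both Xist (means 10.80 and 11.35) and the Y-linked Eif2s3y (8.49 and 7.31) read above the array medians, as a mixture of male and female cells would give. If the cultures were such a mixture, a larger share of female cells in the Blnc1 cultures would raise Xist. The 0.55 (0.40 to 0.71 at 2 SE) goes with that. Loss of the Y chromosome or lower Y transcription alone would leave Xist at its level, whereas its lower bound was 0.399. That bound comes from the same Xist value, which was known when this comparison was chosen, so it is no separate test and does not decide. Genes that escape X inactivation (Kdm6a, Kdm5c, Eif2s3x and Ddx3x) had a median of 0.040, with median bounds of -0.12 and 0.20, which does not decide. As a hypothesis, the vector and Blnc1 populations may differ in the makeup of their cells as well as in Blnc1; an effect of Blnc1 itself on these genes stays open too, since each group may stem from 1 transduced population.

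Brown thermogenic genes were higher, and matrix and preadipocyte genes lower, in camera with the preset correlation, but not with an estimated one (adjusted p = 0.221, 0.221 and 0.341). A more complete differentiation in the Blnc1 cultures could give all 3 shifts. It would also raise general adipocyte genes, but the 18 of these below a vector level of 12, where saturation hides little, had a median log2 fold change of 0.060 (95% bootstrap interval over members -0.089 to 0.11), and 10 of them were positive and 8 negative, so this median does not decide and differentiation stays open. The 3' minus 5' difference separated the groups, lower in both Blnc1 arrays for both transcripts, by -0.13 for Gapdh and -0.170 for Actb. Both lay within the 0.5 set beforehand, but that limit was not tied to the size of the shifts in expression. It cannot decide whether RNA quality had a part in them. A selective effect of Blnc1 on brown genes and a difference in cell makeup stay open as well.

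The 4 arrays can be split into 2 and 2 in 3 ways, and 1 split, the real one, gave as many as 219 probe sets, while the highest of the others gave 0 (limma, adjusted p under 0.05; 491 and 367 probe sets had an unadjusted p under 0.05 there). With so few splits no share under 0.05 can be reached. In the other splits each group held 1 vector and 1 Blnc1 array. The difference between vector and Blnc1 then counted as spread, which by itself lowers the number of calls. The 0 is therefore no measure of what chance would give. All 18 hybridization control probe sets, which read spiked bacterial and phage transcripts, were lower in the Blnc1 arrays (Blnc1 minus vector, median -0.27, range -0.37 to -0.18 log2 units). Between the replicates of a group the same controls differed by medians of -0.24 (Blnc1 replicate 1 minus 2) and -0.12 (vector).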
